A study of Homo sapiens with 30 samples.

How the data were processed

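RNA was measured in 30 libraries of 2 human triple-negative breast cancer cell lines, MDA-MB-436 and Hs 578T, in 10 groups of 3. Per the labels, the groups of each cell line were parental cells in DMSO (diluted 1 in 1000), parental cells given 20 nM paclitaxel for 72 h, and the resistant lines R20A, R20B and R20C, kept in 20 nM paclitaxel. Per the labels' protocols, stranded poly(A) libraries were sequenced paired-end on a HiSeq2000. Per the submitters' processing notes, TopHat2 2.0.8, Cufflinks 2.1.1 and the hg19 assembly were used, without their roles or options. The authors deposited 1 table of FPKM for 23615 gene symbols by 30 libraries. It names no unit itself. Its values were read as FPKM, fragments scaled to transcript length and to the mapped total of each library, which is the unit of the Cufflinks that the authors' notes name. A check of the values against that unit found nothing that contradicted it. Raw reads were not used here. All columns were assigned to a group by their sample names, with 0 unmapped.

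Exact zeros made up 26.1% of the values. An exact 0 can be a failed estimate rather than a silent gene: 96 values of 38 genes, spread over all 30 libraries, were 0 while another library of the same group held at least 20 FPKM. They include FN1, PKM, COL3A1 and genes that cells use constantly such as HNRNPC and PCBP2. Genes listed at 0 are named as such, with their values per library. The table holds no read totals. Relative depth was estimated from low values: where a pair of libraries holds the same small number of fragments of a gene, the ratio of their FPKM is the inverse ratio of their depths, so the peak of these ratios gives it. This estimate was checked on simulated data. FPKM without counts gives no counting interval, so precision is given as the spread between libraries.

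Tests used R 4.3.3 with limma 3.58.1 on log2(FPKM + 1), separately for each cell line, over genes with at least 1 FPKM in at least 3 of its 15 libraries. Group means were fitted to all 5 groups, variances were moderated with a trend on expression, and two-sided p values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Contrasts were the mean of the resistant lines against DMSO, each resistant line against DMSO, 72 h of paclitaxel against DMSO, the mean of the resistant lines against 72 h of paclitaxel, and an F test among the resistant lines. A fit over all 30 libraries tested whether the resistance and the 72 h changes differed between the cell lines (Hs 578T minus MDA-MB-436). Log2 changes are on the log2(FPKM + 1) scale and understate changes of genes near or below 1 FPKM. Group levels are means of FPKM with their SD. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 placed genes and drew the plots.

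27 gene lists with 867 members, 866 of them in the table, were written before the data were examined, as were the contrasts, the rule for naming genes and the alternatives listed first below. They cover drug efflux transporters, tubulins, microtubule-associated proteins, the methionine cycle and one-carbon metabolism, DNA methylation, Polycomb, H3K9 methylation, interferon-stimulated genes, nucleic acid sensing, class I antigen presentation, cancer-testis antigens, oxidative phosphorylation, the TCA cycle, glycolysis, cholesterol biosynthesis, mitosis, DNA replication, p53 targets, the BCL2 family, inflammatory cytokines and NF-kB targets, the integrated stress response, epithelial genes, mesenchymal genes, collagens and matrix, ribosomal proteins, immediate early genes, and leukocyte and endothelial markers. Lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01, and again with the correlation estimated from the data. Camera compares a list with all other genes, so a list can be called in the opposite direction to its median.

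Genes were named by rule. For the resistant mean against DMSO these were the 8 largest rises and 8 largest falls among genes past the threshold there and in each resistant line, changed the same way, with every resistant library on 1 side of every DMSO library and a mean of at least 5 FPKM in either state. For the resistant mean against 72 h of paclitaxel the largest 3 each way were named, for differences among lines the 5 smallest adjusted p with at least 5 FPKM in a line and a range of at least 1 log2 unit, and for the difference between cell lines the 4 largest each way. Up to 4 members per list with the smallest adjusted p were added. ABCB1, TUBB3, EZH2, DNMT1 and MAT2A were always named. Readthrough, antisense, small RNA and unnamed symbols were passed over. Some genes that the rule names are not reported here.

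Replicate numbers were checked for pairing by correlating, over genes, the deviations of same-numbered libraries from their group means. In Hs 578T every pair of every comparison correlated above 0.1 (0.183 to 0.664). In MDA-MB-436 this held for R20A (0.471 to 0.637), R20B (0.416 to 0.634) and paclitaxel for 72 h (0.274 to 0.849) against DMSO, but not for comparisons that include R20C (as low as -0.531 against DMSO, -0.611 against paclitaxel and -0.364 among the lines). The best partner carried the library's own number for 11 of 15 MDA-MB-436 and 14 of 15 Hs 578T libraries. Blocked values are given beside counts that the block moved by more than 1.5 times where the numbers paired; the other paired counts moved by less.

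Positions are those of GRCh37, the assembly of hg19: 20237 symbols were placed by their current symbol and 1533 by an older one, 92.2% in all. Overlaps between resistant lines were set against independent lists and against 100 simulated sets of unchanged groups that share the same DMSO libraries. The tests were run on simulated data with 200 genes changed by known folds. The changed genes were drawn from those above about 5 FPKM in DMSO, so recovery of lower genes was not measured. At 2-fold, 79% were recovered for the resistant mean against DMSO in MDA-MB-436 and 70% in Hs 578T, and for 72 h of paclitaxel 69.5% and 49%. Alternatives were a pseudocount of 0.1, no filter, at least 5 FPKM in 3 libraries, rescaling by median of ratios, the replicate number as a block, robust moderation, a 2-fold threshold, an estimated correlation within lists, fitting the compared groups alone, and leaving out each library in turn. Added after the values were seen were replicates 2 and 3 alone, the block without replicate 3 of R20C of MDA-MB-436, the lists tested on the differences between cell lines, and leaving out the 38 genes with a 0 beside a high value.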

Results

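Poly(A) RNA was sequenced from MDA-MB-436 and Hs 578T, 2 human cell lines derived from triple-negative breast carcinomas, which lack the oestrogen and progesterone receptors and HER2 amplification. Paclitaxel, a taxane that stabilises microtubules and blocks cells in mitosis, was the drug studied. Each cell line gave 5 groups of 3 libraries, 30 libraries in all: parental cells in DMSO, parental cells given 20 nM paclitaxel for 72 h, and 3 lines (R20A, R20B and R20C) grown over months in rising doses until they proliferated in 20 nM paclitaxel. The resistant lines were kept in the drug, so the comparison with DMSO joins the adapted state and the presence of the drug. The comparison with parental cells given the same dose for 72 h separates the long exposure from the short one. Expression was deposited as FPKM for 23615 gene symbols, summing to 378372 to 483320 per library. Between 11148 and 12682 genes reached 1 FPKM in a library. Read totals are not part of the table, but the spacing of low values gave relative depths of 0.76 to 1.388 against the mean of the DMSO libraries of the same cell line.

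**Figure D1:**
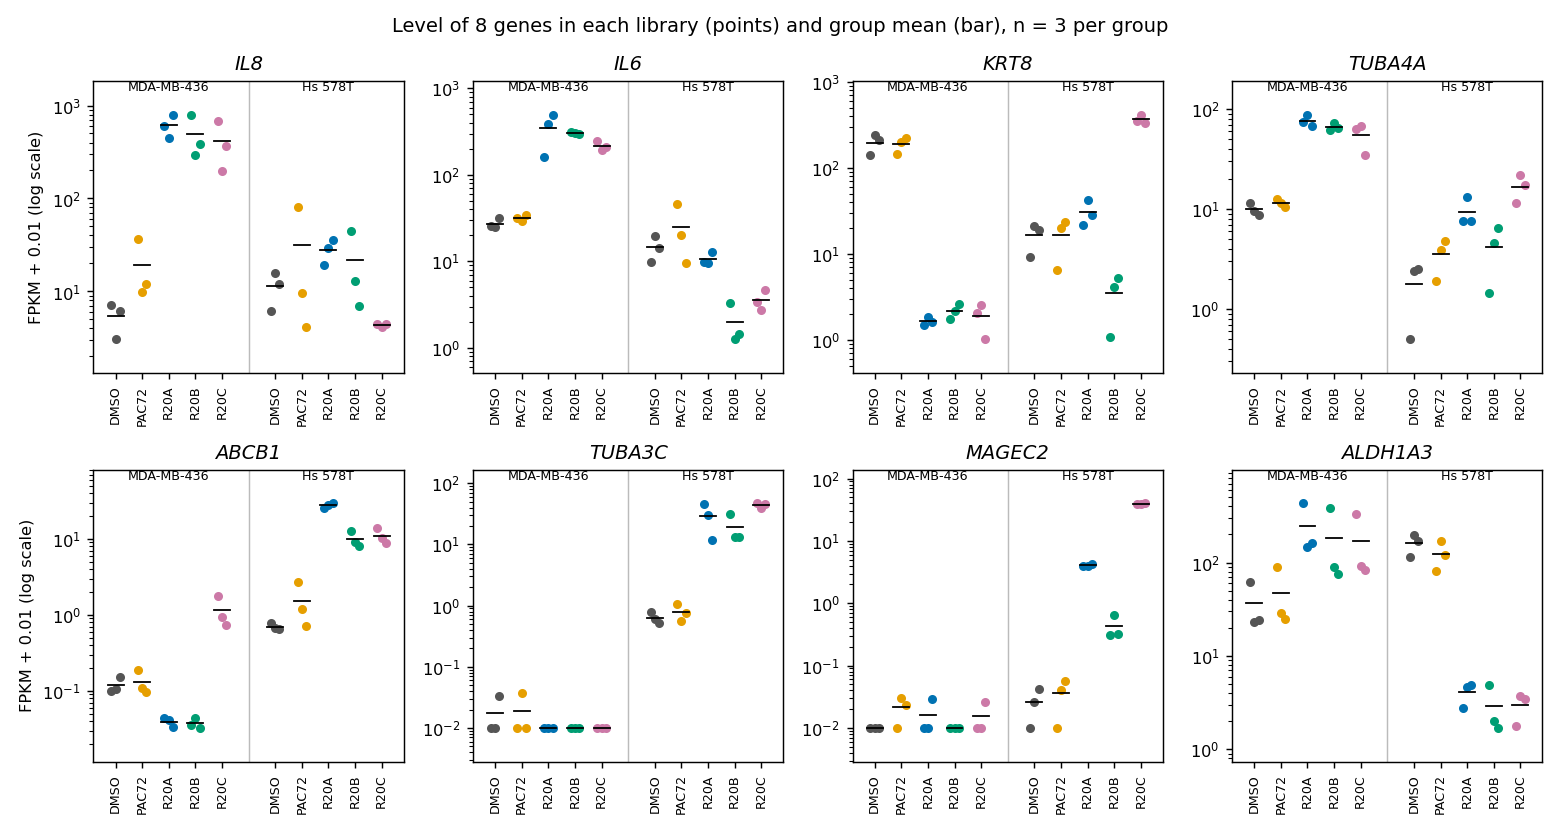
FPKM (with 0.01 added, log axis) of 8 genes in every library, with points for libraries and bars for group means, by cell line and group. IL8 averaged 5.44 FPKM in DMSO and 507 in the resistant MDA-MB-436 libraries, and ABCB1 averaged 0.691 and 16.2 FPKM in Hs 578T.

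The first comparison asked what distinguished the resistant MDA-MB-436 lines from their DMSO-treated parental cells. Secreted inflammatory signals were among the largest rises. IL8, a neutrophil chemokine, averaged 5.44 ± 2.11 FPKM in DMSO (SD, n = 3) and 507 ± 217 in the resistant libraries (SD, n = 9), a log2 change of 6.23 (SE 0.438). CSF3, the granulocyte growth factor, rose from 2.49 to 94.9 FPKM, the chemokine CXCL1 from 2.15 to 56.7, and IL1B, a central inflammatory cytokine, from 39.8 to 690. TNFAIP6, a secreted hyaluronan-binding protein, rose by 4.43 log2 units (SE 0.211). The steroid-metabolising reductases AKR1C1 and HSD11B1 rose by 3.60 and 3.49, and the iron-siderophore carrier LCN2 by 3.32. Each of these genes rose in R20A, R20B and R20C, and all 9 resistant libraries lay above all 3 DMSO libraries, with limma adjusted p between 2.64e-08 and 0.000218.

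On the log2(FPKM + 1) scale the largest fall was in KRT8, the keratin of simple epithelia, from 197 ± 51 FPKM in DMSO (SD, n = 3) to 1.90 ± 0.518 (SD, n = 9), a log2 change of -6.08 (SE 0.195), close to that of CCNG1 (-6.06, SE 0.0777). The added 1 limits the change of genes that fall below 1 FPKM, and by the ratio of mean FPKM CCNG1, HMMR, MAT2B and NUDCD2, below, fell further than KRT8. The KRT8 filament partner KRT18 fell by 1.36, from 276 to 108 FPKM. IL18, an inflammatory cytokine of the IL-1 family, fell from 54.6 to 3.92 FPKM, against the direction of IL1B. The troponin gene TNNC1 fell from 17.2 to 0.329 FPKM and the interferon-induced IFI44 from 68.1 to 6.02. CCNG1 (cyclin G1, a p53 target), HMMR (a spindle-associated hyaluronan receptor), MAT2B (the regulatory subunit of methionine adenosyltransferase 2) and NUDCD2 (a co-chaperone of the dynein pathway) were nearly absent from every resistant library. CCNG1 averaged 68.4 ± 4.31 FPKM in DMSO (SD, n = 3) and lay between 0.0144 and 0.0922 in the 9 resistant libraries. HMMR, at 18.1 ± 1.42 in DMSO, was listed at 0 in 5 of 9 resistant libraries and did not exceed 0.0317. MAT2B, at 16.8 ± 0.888, was listed at 0 in 1 of 9 and did not exceed 0.048, while NUDCD2, at 14 ± 0.79, was listed at 0 in 6 of 9 and did not exceed 0.0901. All of these falls had limma adjusted p between 1.88e-14 and 0.000181.

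CCNG1, NUDCD2, HMMR and MAT2B are neighbours, and RNA alone was measured there. On the GRCh37 assembly they occupy chromosome 5 from 162864575 to 162946564, with CCNG1 at 162864575 to 162873157, NUDCD2 at 162873532 to 162887108 on the opposite strand, HMMR at 162887209 to 162918947 and MAT2B at 162930120 to 162946564. No other gene of the table lies within these 82 kb. The nearest genes above 1 FPKM in DMSO on either side were still expressed. PTTG1 (securin, at 159848862 to 159855746) kept 60.4 to 79.6% of its DMSO level in the resistant libraries, a fall of 0.529 log2 units (limma adjusted p = 0.0016). WWC1 (167718650 to 167899308) kept 64.4 to 103.9% and did not pass (limma adjusted p = 0.287). Of the next expressed genes outward, PANK3 rose by 0.609 (limma adjusted p = 0.0047), while C5orf54, SLU7 and RARS did not pass. Genes listed near PTTG1 that met the naming rule also fell: MED7 (-1.025), THG1L (-1.255), CLINT1 (-0.706), RNF145 (-0.804) and TTC1 (-0.646). Beyond PANK3, CREBRF (1.22), STC2 (1.16) and TRIM7 (1.104) rose and ARL10 (-1.228) fell. That rule keeps only changed genes, and these were looked up after their values were seen. Between MAT2B and WWC1 lies TENM2 (166406034 to 167691162), at 0.473 FPKM in DMSO and 5.01, 3.39 and 1.29 in R20A, R20B and R20C. In Hs 578T the same genes were expressed in all groups, and MAT2B fell only from 46.2 to 32.2 FPKM (limma adjusted p = 0.006).

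**Figure D2:**
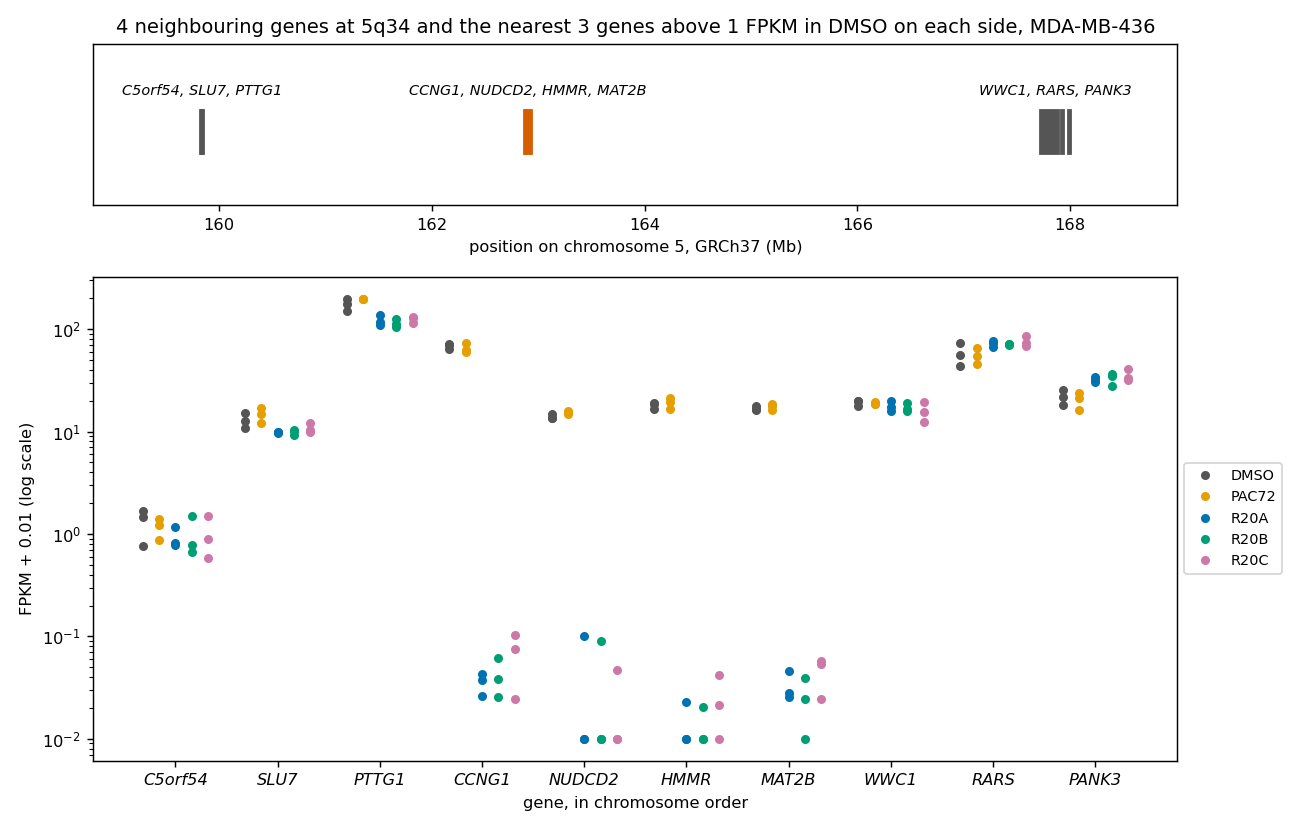
Map of the chromosome 5 interval (GRCh37, position in Mb) above the FPKM (with 0.01 added, log axis) of its genes and of the nearest genes above 1 FPKM in DMSO in each MDA-MB-436 library, a point per library, coloured by group. CCNG1, NUDCD2, HMMR and MAT2B kept at most 0.645% of their DMSO level in any of the 9 resistant MDA-MB-436 libraries.

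Gene groups fixed in advance moved apart in these lines. Of 29 inflammatory cytokine and NF-kB target genes 20 rose and none fell (20 adjusted over the list alone), with a median log2 change of 1.20. IL6 rose from 27.1 to 288 FPKM and the mitochondrial superoxide dismutase SOD2 from 290 to 583. The camera adjusted p of this list was 1.04e-09, and the adjusted p = 0.525 with an estimated correlation. Of 40 interferon-stimulated genes 25 fell and 3 rose (25 and 3 adjusted over the list alone), with a median of -0.68. HERC5, the ligase for ISG15, fell by 1.54 and HERC6 by 1.1, while the interferon-induced GTPase GBP1 rose by 1.57. This list had a camera adjusted p = 1.04e-09, and an adjusted p = 0.531 with an estimated correlation. Of 26 integrated stress response genes 10 rose and none fell (13 adjusted over the list alone), at a median of 0.66. The stress transcription factor ATF3 rose by 1.28, STC2 by 1.16, XBP1 by 0.73 and the chaperone HSPA5 by 0.60. DDIT3 rose by 0.86, while ATF4 (limma adjusted p = 0.536), ASNS, TRIB3 and CHAC1 did not pass, 5 members chosen after their values were seen. Its camera adjusted p was 6.98e-05, or an adjusted p = 0.701 with an estimated correlation. Of 74 cytosolic ribosomal protein genes 19 fell and 1 rose (20 and 1 adjusted over the list alone), with a median of -0.35, a camera adjusted p = 2.72e-07 and an adjusted p = 0.802 with an estimated correlation. RPL27A fell by 1.59 and RPL5 by 0.86, whereas RPS23 rose by 0.54. Of genes listed beside RPL27A that met the naming rule, EIF3F (-1.255), TMEM9B (-1.236), AKIP1 (-1.296) and TMEM41B (-1.061) fell and NRIP3 (0.532) rose. Chromosome 5, which holds RPS23, stood higher as a group (below). Position was not separated from list membership. Camera called 4 lists here and 7 without DMSO replicate 3.

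**Figure D3:**
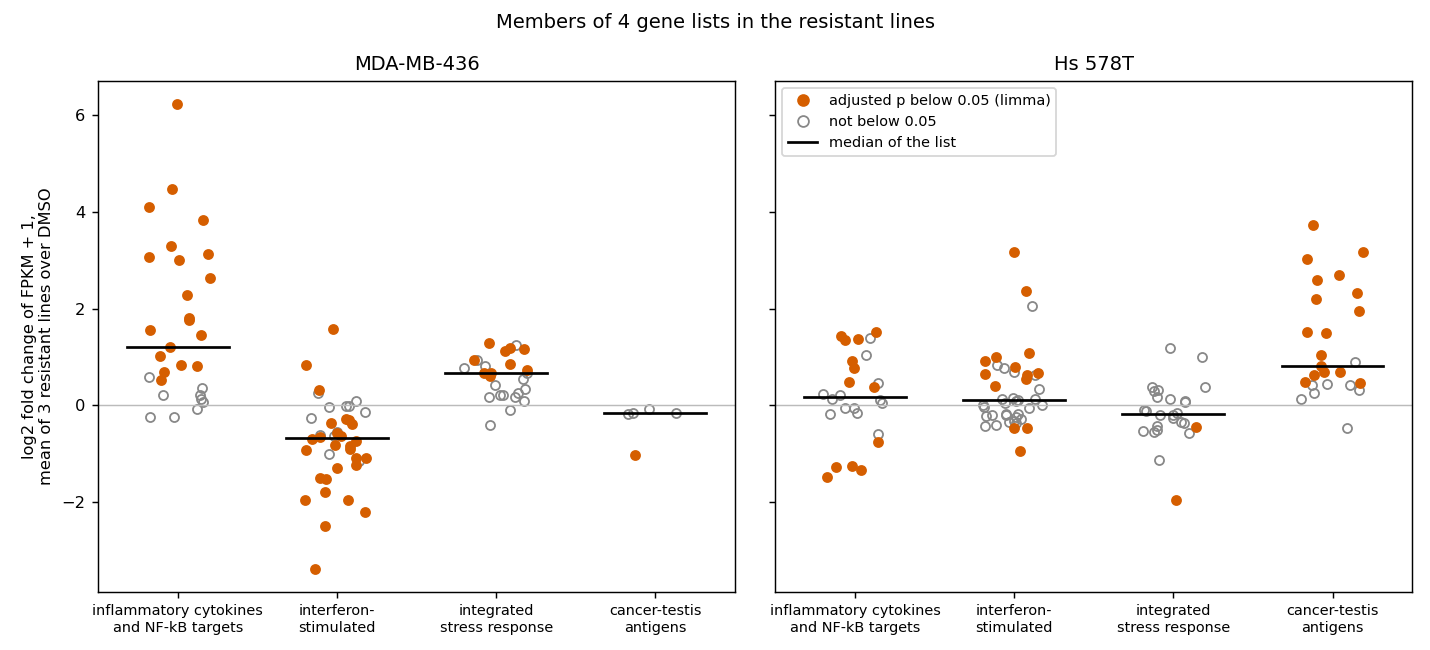
Log2 changes (resistant mean minus DMSO, on log2(FPKM + 1)) of the members of selected gene lists in both cell lines, a point per gene with the list median as a line. The median of the interferon-stimulated genes was -0.68 in MDA-MB-436 and 0.10 in Hs 578T.

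Drug and microtubule genes changed singly rather than as groups. ABCB1, the P-glycoprotein efflux pump, stayed below the expression filter in MDA-MB-436 and was not tested: it lay between 0.0914 and 0.143 FPKM in DMSO, at 0.0343 or below in R20A and R20B, and between 0.727 and 1.77 in R20C. Of 8 tested efflux transporters only ABCC4 passed, falling by 0.32 (0 adjusted over the list alone). Of 15 tubulins 1 rose, the alpha-tubulin TUBA4A, from 9.95 ± 1.41 to 66.0 ± 14.2 FPKM (SD, n = 3 and n = 9; limma adjusted p = 3.71e-07). The neuronal beta-tubulin TUBB3 was at 87.4 ± 42.7 and 50.2 ± 17.6 FPKM and did not pass (limma adjusted p = 0.27). Of 27 microtubule-associated genes 6 rose and 2 fell, among them the plus-end protein CLIP1 (0.85), MAP7 (0.77) and MAP1B (0.56), with the tubulin tyrosine ligase TTL down by 0.48. The medians of these 3 lists were -0.12, 0.01 and 0.08, and their camera adjusted p values were 0.683, 0.771 and 0.455.

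Methionine and chromatin genes were examined because the series title names metabolism and epigenetics. Of 34 genes of the methionine cycle and one-carbon metabolism 4 rose and 5 fell (median -0.18, camera adjusted p = 0.329). Besides MAT2B, the homocysteine methyltransferase BHMT2 rose from 40.8 to 113 FPKM and the methionine synthase reductase MTRR fell from 29.1 to 14.6. MAT2A, the catalytic partner of MAT2B, fell by 0.50, from 136 to 96.3 FPKM (limma adjusted p = 0.0197), and spermine synthase SMS fell by 0.70. DNMT1, the maintenance DNA methyltransferase, fell by 0.34 (limma adjusted p = 0.0207), and TET3 rose by 0.33. These were the only 2 of 16 DNA methylation genes to pass, while EZH2, the H3K27 methyltransferase, stood at 42.9 and 49.8 FPKM (limma adjusted p = 0.156). Of 28 Polycomb genes 1 rose (PCGF1, 0.45) and 2 fell (RNF2, -0.62, and MTF2, -0.58). Of 20 H3K9 methylation genes 3 rose (MPHOSPH8, KDM4C and KDM4A, by 0.59, 0.50 and 0.34; 2 adjusted over the list alone). The medians of these last 3 lists were -0.00, -0.10 and -0.01, with camera adjusted p of 0.867, 0.447 and 0.867, and the H3K9 list's mean of 0.02 had the opposite sign to its median.

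Other lists were not called by camera in MDA-MB-436. Among 21 nucleic acid sensors 1 rose and 7 fell (median -0.11, camera adjusted p = 0.103), including the RNA sensor IFIH1 (-0.98) and the STING gene TMEM173 (-1.50), with IFI16 up by 0.80. In antigen presentation 3 of 18 genes rose, PDIA3, ERAP1 and ERAP2, and the class I transactivator NLRC5 fell (median 0.03, adjusted p = 0.462 by camera). Of 5 cancer-testis antigens 1 fell, CSAG2 (list median -0.17, camera adjusted p = 0.131). In oxidative phosphorylation 5 of 78 genes rose and 12 fell, with COX5A up by 0.80 and SDHC down by 0.70 (median -0.09, camera adjusted p = 0.329). In the TCA cycle 3 of 28 rose and 2 fell (median 0.03), with the pyruvate dehydrogenase kinase PDK1 up by 1.02 (camera adjusted p = 0.867 for the list). OGDH fell by 0.95. Glycolysis had 3 of 25 up, HK2, PKM and SLC2A3, and 3 down (median 0.15, camera adjusted p = 0.447). In cholesterol synthesis 5 of 24 rose and none fell (median 0.23, camera adjusted p = 0.103), CYP51A1 by 1.02.

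Among 40 mitosis and spindle checkpoint genes 8 rose and 5 fell (median -0.10), with CDC25C up by 0.82, CCNB1 up by 0.46 and PTTG1 down by 0.53. DNA replication had 3 of 43 up and 4 down (median -0.16), p53 targets 5 of 26 up and 4 down, and the BCL2 family 3 of 15 up and 3 down. The death receptor TNFRSF10B rose by 0.82 and the BH3-only gene BMF by 0.80, while PMAIP1 fell by 0.80 and HRK by 0.73. The p53 list had a median of 0.02 and a mean of -0.11, and the test pointed up, CCNG1 being a member. Epithelial genes (4 of 15 up, 3 down) also had a median and mean of opposite sign, 0.01 and -0.37, with KRT8 a member and the test pointing down. Of 24 mesenchymal genes 8 rose and 5 fell (median 0.36), ZEB2 by 0.93, against TAGLN (-2.27) and AXL (-0.83). Collagens and matrix genes had 8 of 25 up and 5 down (median 0.18), with LAMB3 up and LAMB1 and TNC down. Immediate early genes had 5 of 21 up and none down (median 0.27), NR4A2 by 1.58. The camera adjusted p of these lists lay between 0.103 and 0.867. Adjusted over the list alone the p53, BCL2, mesenchymal, collagen and immediate early counts were 8 and 4, 4 and 3, 9 and 6, 8 and 6, and 5 and 1. Leukocyte and endothelial markers had under 5 tested members, of which KDR (-0.51) and CD14 (-1.11) fell.

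Over all genes 3086 of 12236 tested passed in the resistant mean against DMSO, 1766 up and 1320 down (limma, Benjamini-Hochberg adjusted), and 448 of them changed at least 2-fold. R20A gave 2189, R20B 2395 and R20C 2086 genes, and 1528 passed in all 3 lines in the same direction, 936 up and 592 down. Replicate numbers paired the libraries for R20A and R20B against DMSO, and with the number as a block these gave 3337 and 3622. With the compared groups alone in the fit R20B gave 1519 and R20C 858. Replicate 3 of R20C stood apart from the other resistant libraries, and with the block and without it the resistant mean gave 6200 genes. Without DMSO replicate 2 the resistant mean gave 2048, R20C 1330 and all 3 lines together 1012. The 3 lines resembled each other: across the tested genes, which are not independent replicates, the log2 changes correlated at 0.948 for R20A with R20B, 0.831 for R20A with R20C and 0.838 for R20B with R20C. Unchanged groups simulated against the same DMSO libraries gave about 0.50, and the observed covariances of 0.243, 0.211 and 0.213 exceeded the simulated ones by 0.209, 0.177 and 0.179. Of the genes that rose, 1140 were shared by R20A and R20B, against 147.3 for independent lists. Part of the excess may come from the shared controls, which are too few to split. Nothing in the labels says that replicates were separate cultures, so these p values measure the spread between these samples, which may be technical.

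Differences among the 3 resistant MDA-MB-436 lines were few. The limma F test called 14 genes (370 at an unadjusted p under 0.05), 5 of them with a range of at least 1 log2 unit. BST2, the interferon-induced tetherin, averaged 33.3 ± 7.80 FPKM in R20A, 2.83 ± 0.482 in R20B and 15.3 ± 6.43 in R20C (SD, n = 3 each; limma adjusted p = 0.000873). CCL2, a monocyte chemokine, stood at 8.97 FPKM in R20B against 1.26 and 1.37 in R20A and R20C. The teneurin TENM2 was at 5.01, 3.39 and 1.29 FPKM and ZNF622 at 32.5, 51.4 and 23.0 in R20A, R20B and R20C. The fifth, the interferon-induced SAMD9, did not reach the level set for naming and was chosen after its values were seen. Leaving out single libraries gave between 2 and 19 genes. Those 2, without replicate 2 of R20B, were BST2 and BASP1, and with the resistant lines alone in the fit 2 passed, BST2 and SNORD94. BASP1 and SNORD94 were chosen after their values were seen.

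The next comparison asked what 72 h of 20 nM paclitaxel did to parental MDA-MB-436 cells. No single gene passed (limma; 82 of 12236 at an unadjusted p under 0.05), so single genes are given as values only. TUBB3 averaged 87.4 and 98.6 FPKM in DMSO and paclitaxel, EZH2 42.9 and 42.7, DNMT1 46.2 and 43.4, and MAT2A 136 and 127, all with a limma adjusted p of 1. Small shifts of whole lists were called by camera for 9 of 26 lists and none of the 9 was called with an estimated correlation. Immediate early genes (median 0.28) and inflammatory genes (0.25) stood above the other genes, with camera adjusted p of 2.56e-12 and 6.71e-11, as did p53 targets (0.07, 0.0256) and interferon-stimulated genes (0.10, 0.002). DNA replication genes stood below (-0.12, camera adjusted p = 3.73e-15), as did cholesterol synthesis (-0.17, 1.15e-07), the methionine cycle (-0.07, 0.00757), oxidative phosphorylation (-0.04, 0.012) and the TCA cycle (-0.04, 0.0342). With an estimated correlation the adjusted p was 0.0832 for the immediate early, inflammatory, p53, replication and methionine lists, 0.285 for cholesterol synthesis, 0.70 for the TCA cycle, 0.744 for the interferon-stimulated genes and 0.966 for oxidative phosphorylation. No member of any list passed over all genes, and adjusted over the list alone 1 microtubule-associated gene rose, MAP7 (0.52), chosen after its values were seen. Without replicate 1 of the treated cells the median of oxidative phosphorylation was 0.05 and that of ribosomal proteins 0.12. In simulated libraries with 2-fold changes 69.5% of changed genes were recovered in this comparison.

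Resistant MDA-MB-436 lines were then set against parental cells given the drug for 72 h. IL8 rose from 19.3 ± 14.7 to 507 ± 217 FPKM (SD, n = 3 and n = 9), TNFAIP6 from 1.00 to 30.5 and CXCL1 from 3.82 to 56.7. The log2 changes were -6.03 for KRT8, -5.99 for CCNG1 and -4.30 for HMMR, which stood at 18.9 FPKM after 72 h. In this comparison 2890 genes passed (limma, adjusted), 1634 up and 1256 down, and 1880 without replicate 2 of the treated cells. Camera called 5 lists, of which none was called with an estimated correlation. Interferon-stimulated genes (24 of 40 fell, 3 rose, median -0.72, adjusted p = 0.402 with an estimated correlation) and ribosomal proteins (14 of 74 fell, 1 rose, -0.32, adjusted p = 0.862) were lower. Inflammatory genes (15 of 29 rose, 1 fell, 0.81, adjusted p = 0.402), the integrated stress response (10 of 26 rose, 0.53, adjusted p = 0.708) and cholesterol synthesis (9 of 24 rose, none fell, 0.38, adjusted p = 0.708, all by camera with an estimated correlation) were higher.

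In Hs 578T the resistant lines differed from DMSO-treated parental cells in another set of genes. PDPN (podoplanin, a membrane mucin of lymphatic and mesenchymal cells) averaged 0.353 ± 0.22 FPKM in DMSO (SD, n = 3) and 99.0 ± 74.9 in the resistant libraries (SD, n = 9), a log2 change of 5.89 (SE 0.298). Among the other large rises, the fibril-associated collagen COL14A1 rose from 2.26 to 136 FPKM, the heparan sulfatase SULF2 from 0.139 to 56.8, the protease inhibitor A2M from 0.0390 to 54.7 and the selenium carrier SEPP1 from 0.876 to 86.8. SLPI, a leukocyte protease inhibitor listed at 0 in 1 DMSO library, reached 153 FPKM in R20A, 3.85 in R20B and 62.3 in R20C. PI15 was highest in R20B (251 FPKM, against 22.5 and 14.4), and the transcription factor FOXF1 rose from 0.0691 to 23.3 FPKM. ALDH1A3, a retinaldehyde dehydrogenase often used as a stem cell marker in breast cancer, fell from 161 ± 43.7 to 3.30 ± 1.32 FPKM (SD, n = 3 and n = 9), a log2 change of -5.26 (SE 0.287). The transcriptional adaptor LMO2 fell from 19.3 to 0.423 FPKM, the matrix protease ADAMTS1 from 69.6 to 7.24, EMB from 31.7 to 3.91, SPTLC3 from 26.2 to 2.95, the integrin ITGA8 from 27.1 to 3.98 and GALNT3 from 26.6 to 3.29. The carboxypeptidase inhibitor LXN averaged 11.7 FPKM in DMSO and was listed at 0 in 8 of 9 resistant libraries. These 16 genes had limma adjusted p between 2.9e-09 and 3.38e-05.

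ABCB1 rose in Hs 578T. It averaged 0.691 ± 0.07 FPKM in DMSO (SD, n = 3) and 27.8 ± 1.87 in R20A, 10.0 ± 2.42 in R20B and 11 ± 2.50 in R20C (SD, n = 3 each), a log2 change of the resistant mean of 3.19 (SE 0.203, limma adjusted p = 5.69e-08). After 72 h of paclitaxel it stood at 1.53 ± 1.03 FPKM (SD, n = 3; limma adjusted p = 1). The gene lies at 87132333 to 87342639 (GRCh37) on chromosome 7, whose genes as a group stood higher in all 6 resistant lines. In Hs 578T that group difference was 0.451, 0.571 and 0.285 log2 units in R20A, R20B and R20C, far below the change of ABCB1. Some genes near ABCB1 also rose in Hs 578T, KIAA1324L by 2.35, ADAM22 by 1.95 and RUNDC3B by 0.94. Others between or beside them, CROT, SLC25A40, DBF4 and SRI, did not pass. These neighbours were chosen after their values were seen. Of 12 efflux transporters 4 rose and 1 fell (4 and 2 adjusted over the list alone), including ABCC4, from 6.25 to 13.1 FPKM, ABCC2, at 0.305 FPKM in DMSO and 0.79, 0.304 and 8.27 in R20A, R20B and R20C, and a fall of ABCG2 from 2.71 to 0.342 FPKM. The median of this list was 0.12 (camera adjusted p = 0.875). Of 17 tubulins 5 rose and none fell (median 0.17, camera adjusted p = 0.552). TUBA3C, of a testis-type alpha-tubulin family whose copies share reads and are uncertain singly, rose from 0.626 to 30.9 FPKM, TUBB4A from 0.624 to 11.1 and TUBA4A from 1.79 to 10.1. TUBB3 was at 110 and 115 FPKM and did not pass (limma adjusted p = 0.831). Of 27 microtubule-associated genes 4 rose and 5 fell (median -0.05, camera adjusted p = 0.19), with MAP4 down from 124 to 72.4 FPKM, MAPRE2 and MAP2 down by 0.84 and 1.21, and STMN3 up by 1.28.

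Cancer-testis antigens, genes normally expressed in the germ line, were the Hs 578T list that moved furthest: 17 of 25 rose and none fell (22 adjusted over the list alone), with a median of 0.81 and a camera adjusted p = 1.03e-08, but an adjusted p = 0.0549 with an estimated correlation. GAGE2A rose from 17.3 to 249 FPKM and PAGE1 from 0.333 to 19.7. Members near 0 in DMSO, such as PAGE1 and MAGEC2 (at most 0.0318 FPKM there), passed the filter only through resistant lines where they were high. Such members had little room to fall, so the absence of falls is partly fixed by the filter. The GAGE copies share reads and are uncertain singly. In R20C alone 22 of the 25 rose (24 adjusted over the list alone), at a median of 1.84 (camera adjusted p = 3.68e-12, and adjusted p = 0.0172 with an estimated correlation). R20A had 13 up and none down (camera adjusted p = 1.41e-06, and adjusted p = 0.133 with an estimated correlation), and R20B 6 up and 3 down (camera adjusted p = 0.287). 3 markers of other cell types stood in the same order, R20C, R20A and R20B: LCP1 at 263, 49.2 and 1.48 FPKM, TEK at 10.1, 3.84 and 0.0945, and CD3D at 4.65, 0.729 and 0. Of other leukocyte genes, chosen after their values were seen, SRGN fell, from 115 FPKM in DMSO to 22.2, 47.3 and 14.6 in these lines, PTPRC and LYZ stayed below 0.1 in DMSO, R20A and R20C, and HLA-DRA rose, from 0 in DMSO to 7.36 in R20C and 3.36 in R20A. The order held for the medians of 12 genes expressed in MDA-MB-436 but not in parental Hs 578T, at 8.94, 1.98 and 0.378% of their MDA-MB-436 level. Of the cancer-testis list only MAGEA4, MAGEA10, DDX43, CSAG2 and PRAME passed the expression filter in MDA-MB-436. MAGEC2 did not exceed 0.0205 FPKM in any MDA-MB-436 library and lay between 38.6 and 39.9 in Hs 578T R20C. These values argue against MDA-MB-436 RNA as the source for the other members of the list. RNA from a further cell line was not excluded for these cancer-testis rises. Of 18 antigen presentation genes 3 rose and 2 fell (median 0.07, test down), the class I genes HLA-B, HLA-F and HLA-C rising by 2.26, 2.06 and 1.19. Reads of the class I genes can also be shared between copies. Of 42 interferon-stimulated genes 11 rose and 3 fell (median 0.10), OAS3 by 1.07 and MX1 by 0.67, with BST2 at 1.06 FPKM in DMSO, 40 in R20A, 1.06 in R20B and 82.8 in R20C. Of 21 nucleic acid sensors 3 rose and 1 fell, TLR3 by -0.95 (median -0.03, mean 0.10, test down). Camera gave an adjusted p = 0.875 for each of these 3 lists.

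3 further lists were called by camera in Hs 578T, none with an estimated correlation. Mesenchymal genes had 5 of 30 up and 12 down (5 and 13 adjusted over the list alone; median -0.32, camera adjusted p = 0.00603, and adjusted p = 0.9 with an estimated correlation). N-cadherin, CDH2, fell from 167 to 47.8 FPKM and PRRX1 fell by 1.1, while S100A4 rose from 19.9 to 344 FPKM and FAP by 1.56. Ribosomal proteins had none of 74 up and 10 down (0 and 5 adjusted over the list alone; median -0.16, camera adjusted p = 0.00183, and adjusted p = 0.969 with an estimated correlation), with RPL14 and RPSA both down by 0.81. DNA replication had 1 of 43 down, POLE2 by -0.73, and none up (0 adjusted over the list alone; median -0.32, camera adjusted p = 0.00496, and adjusted p = 0.969 with an estimated correlation).

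The remaining lists were not called. In the BCL2 family 4 of 13 rose and 1 fell (median 0.61, camera adjusted p = 0.19), including the death-promoting BH3-only genes BMF, from 0.651 to 14.1 FPKM, and BCL2L11, from 1.23 to 3.48, and the survival gene BCL2, from 0.149 to 1.76. Collagens and matrix genes had 11 of 35 up and 4 down (median 0.39, camera adjusted p = 0.383), the matrix glycoprotein TNC from 3.56 to 86.7 FPKM, against its fall in MDA-MB-436. Epithelial genes had 7 of 14 up and 4 down (median 0.61), with KRT17 at 0.076 FPKM in DMSO, 23.0 in R20A, 0.0125 in R20B and 100 in R20C, and KRT7 down by 1.76. Of 27 p53 targets 5 rose and 2 fell (median 0.18), with CDKN1A, the p21 cell cycle inhibitor, up from 11.2 to 36 FPKM. Inflammatory genes had 8 of 26 up and 5 down (median 0.17), CCL2 from 11.1 to 32.5 FPKM, and the integrated stress response had none of 26 up and 2 down (median -0.17, camera adjusted p = 0.0998), STC2 from 195 to 59.2. Immediate early genes had 5 of 22 up and 2 down (median 0.22), with MYC down from 49.6 to 22.2 FPKM. Mitosis genes had 1 of 40 up, MAD1L1, and none down (median -0.10, camera adjusted p = 0.181). Leukocyte and endothelial markers had 3 of 6 up and none down (median 0.77, camera adjusted p = 0.0923) by the resistant mean. LCP1 stood at 1.97 FPKM and TEK at 0.00213 in DMSO, and CD3D was listed at 0 in all DMSO and R20B libraries. The levels of these 3 genes in the lines are given with the cancer-testis antigens. TEK and CD3D passed the filter only through resistant lines and had no room to fall. Camera adjusted p for the matrix, epithelial, p53, inflammatory and immediate early lists lay between 0.383 and 0.944. Adjusted over the list alone the epithelial, stress response, mitosis and leukocyte counts were 8 and 4, 0 and 1, 0 and 0, and 4 and 0.

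Metabolic lists moved little in Hs 578T. Glycolysis had 2 of 25 up and 4 down (median -0.20, camera adjusted p = 0.133), with the glucose transporter SLC2A3 up from 0.299 to 13.4 FPKM and LDHA down by 1.04. The TCA cycle had 5 of 29 up and 4 down (median 0.06, test down), oxidative phosphorylation 4 of 78 up and 7 down (median 0.06, test down) and cholesterol synthesis 3 of 24 up and 1 down (median 0.30), TM7SF2 by 1.13. The methionine list had 4 of 35 up and 4 down (median -0.19), MAT2B by -0.52. DNA methylation genes had 1 of 17 up and 2 down, MBD2 by -0.88 (median -0.00), Polycomb genes 4 of 28 up and 1 down, the H3K27 demethylase KDM6B by 1.30 (median 0.14, test down), and H3K9 genes 1 of 20 up and 1 down (median 0.09, test down). Camera adjusted p for these 7 lists lay between 0.336 and 0.875. Adjusted over the list alone the TCA, oxidative phosphorylation, methionine and Polycomb counts were 6 and 4, 3 and 4, 4 and 3, and 2 and 1. EZH2, DNMT1 and MAT2A did not pass, at 11.9 and 13.9, 45.3 and 49.3, and 86.7 and 72.2 FPKM (limma adjusted p = 0.878, 0.914 and 0.496).

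Over all genes 4094 of 13137 passed in the resistant mean of Hs 578T (limma, adjusted), 2817 up and 1277 down, and 1283 changed at least 2-fold. R20A gave 2868 genes, R20B 2944 and R20C 4922, and 941 passed in all 3 lines in the same direction, 669 up and 272 down. With the replicate number as a block, since the numbers paired these libraries, R20A gave 4572, R20B 5020 and all 3 lines 1654. With the compared groups alone in the fit R20A gave 1789 and R20B 1769. The replicate 1 libraries stood apart, and without them the resistant mean gave 6927 genes. Single libraries moved the counts of R20A (1862 without its replicate 2 and 1905 without its replicate 3), of R20B (1806 without its replicate 2 or 3, 1863 without DMSO replicate 2) and of all 3 lines (612 without DMSO replicate 2). Rescaling by median of ratios moved the median log2 change by -0.128 in R20A, -0.126 in R20C and 0.0355 in R20B. It lowered the share of calls that rose from 68.8 to 58.7% for the resistant mean, from 77.4 to 63.3% for R20A and from 69.1 to 56.7% for R20C, and raised it from 51.7 to 56.5% for R20B. Between 12000 and 12525 genes reached 1 FPKM in R20A and 12343 to 12682 in R20C, against 11148 to 11211 in DMSO. In R20C 12 genes expressed in MDA-MB-436 but not in parental Hs 578T stood at a median of 8.94% of their MDA-MB-436 level, with 4 of the 12 under 1%, against medians of 1.98% in R20A, 0.378% in R20B and 0.468% in DMSO. Pairwise correlations of log2 changes across genes were 0.591, 0.728 and 0.536 (R20A with R20B, R20A with R20C, R20B with R20C), with about 0.5 from simulated unchanged groups. Their covariances exceeded the simulated ones by 0.265, 0.447 and 0.314, and 826, 1607 and 949 genes rose in each pair against 257.1, 574.6 and 394.1 for independent lists.

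**Figure D4:**
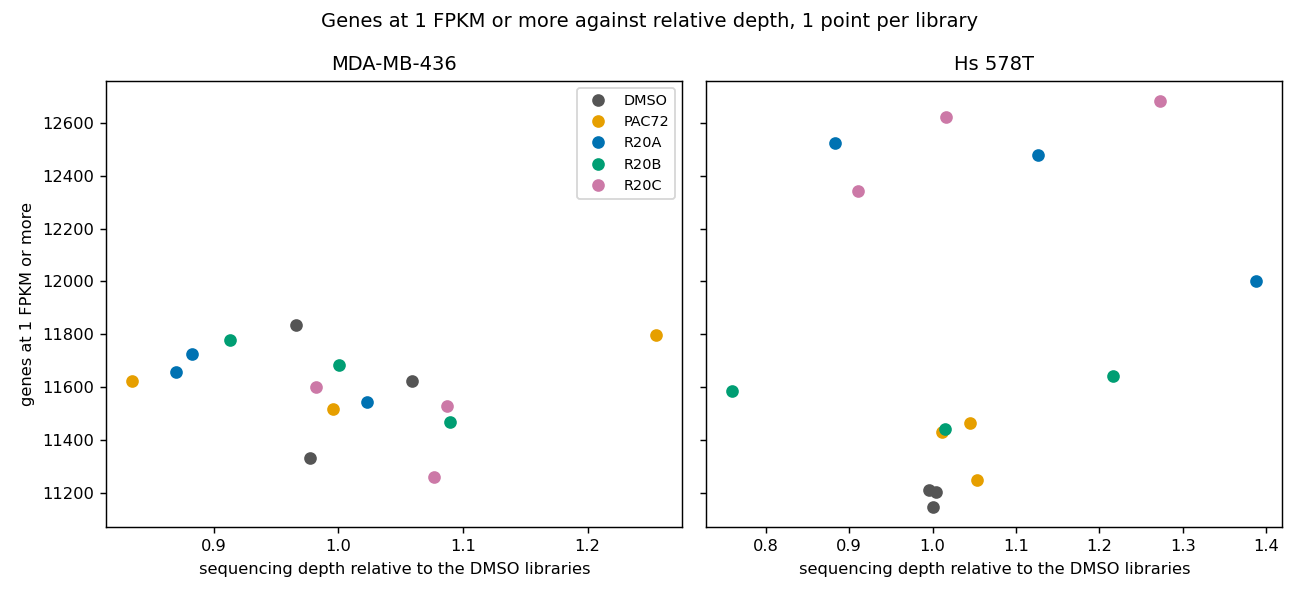
Genes at 1 FPKM or more (vertical) against relative sequencing depth (horizontal, DMSO mean at 1), a point per library coloured by group, for each cell line. The Hs 578T libraries of R20A and R20C hold at least 12000 genes at 1 FPKM, and its DMSO libraries at most 11211.

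The 3 resistant Hs 578T lines differed from each other in 5350 genes (limma F test, adjusted; 8068 with the block), 2584 of them by at least 1 log2 unit. MAGEC2, a cancer-testis antigen, averaged 39.2 ± 0.644 FPKM in R20C, 4.04 ± 0.234 in R20A and 0.415 ± 0.187 in R20B (SD, n = 3 each; limma adjusted p = 6.5e-11). MAGEA11 followed the same order at 18, 4.95 and 0.0819 FPKM, and PNMA5 stood at 35.2, 0.715 and 0.00869 and was listed at 0 in 2 R20B libraries. MPZL2 was at 10.6, 1.64 and 0.0401 FPKM. PARM1 was instead highest in R20A, at 33.7 ± 3.31 FPKM, against 1.58 and 1.73 in R20B and R20C.

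Paclitaxel for 72 h changed no gene in parental Hs 578T cells past the threshold (limma; smallest adjusted p 0.139, 399 of 13137 at an unadjusted p under 0.05). With the replicate number as a block 3 genes passed, the histone genes HIST1H2BK and HIST1H2BC and PRR4, higher by 1.88, 1.55 and 1.46 and chosen after their values were seen (limma adjusted p = 0.00982, 0.00982 and 0.0437). TUBB3, EZH2, DNMT1 and MAT2A averaged 125, 11.8, 36.3 and 96.6 FPKM, each with a limma adjusted p of 1. Camera called 11 of 27 lists, none with an estimated correlation, and 5 without DMSO replicate 3 or replicate 1 of the treated cells. DNA replication (median -0.47, 1.2e-11), cholesterol synthesis (-0.33, 6.57e-08), oxidative phosphorylation (-0.14, 2.27e-07), the TCA cycle (-0.15, 0.00104), the methionine cycle (-0.12, 0.0108), mitosis (-0.16, 0.0015), mesenchymal genes (-0.11, 0.00104) and ribosomal proteins (-0.08, 0.00274) stood below the other genes (camera adjusted p). Immediate early (0.30, 0.000245), inflammatory (0.20, 0.0114) and interferon-stimulated genes (0.13, 0.0458) stood above (camera adjusted p). With an estimated correlation the camera adjusted p of these 11 lists lay between 0.611 and 0.885. No member passed over all genes, and adjusted over the list alone ACTA2, CTGF, FN1 and KRT7 fell and NR4A2 rose, 5 genes chosen after their values were seen. FN1 (fibronectin), a mesenchymal member, was listed at 0 in 2 of the 3 treated libraries and at 1459 FPKM in the other, against 1615 to 3193 in DMSO, and the list's mean of -0.42 holds these values. Leaving out replicate 1 of the treated cells turned the median of the inflammatory list to -0.12 and that of the ribosomal list to 0.17.

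Against parental cells given the drug for 72 h, the resistant Hs 578T lines gave 4128 genes (limma, adjusted), 2770 up and 1358 down, 67.1% of them up and 57.1% after rescaling, and 2684 without replicate 2 of the treated cells. PDPN rose by 5.85, SULF2 by 5.21 and COL14A1 by 5.04, and ALDH1A3 fell by 4.87, ADAMTS1 by 3.43 and LXN, from 18 ± 8.30 FPKM (SD, n = 3), by 4.13. Only the cancer-testis antigens were called by camera, with 18 of 25 up and none down (20 adjusted over the list alone; median 0.85, adjusted p = 9.7e-09, and adjusted p = 0.0544 with an estimated correlation).

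The cell lines were then compared in how they differed from their own parental cells. Across 11505 genes tested in both, which are not independent replicates, the resistant log2 changes correlated at 0.03 (Pearson) and 0.04 (Spearman). Genes that rose in both numbered 361 against 277.4 for independent lists, 142 fell in both against 115.5, and 416 moved in opposite directions against 361.4. The changes after 72 h of paclitaxel correlated at 0.36 (Pearson) and 0.416 (Spearman) across the same genes. A direct test of the difference called 4199 of 13916 genes for resistance (limma, adjusted), 2542 higher in Hs 578T, and none for the 72 h response (159 at an unadjusted p under 0.05). KRT8 differed by 7.19 log2 units (SE 0.462), falling in MDA-MB-436. In Hs 578T it stood at 16.5 FPKM in DMSO and moved apart among the lines, at 31 in R20A, 3.47 in R20B and 366 in R20C. SULF2 differed by 6.17, S100A4 by 5.72 and CCNG1 by 5.62. ALDH1A3 differed by -7.51 (SE 0.70), rising from 36.5 to 199 FPKM in MDA-MB-436 against its fall in Hs 578T. IL8 differed by -5.99, TNFAIP6 by -5.45 and IL6 by -4.79, IL6 standing at 14.5 and 5.43 FPKM in the DMSO and resistant Hs 578T libraries. These 8 genes had limma adjusted p between 5.99e-15 and 6.28e-06.

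**Figure D5:**
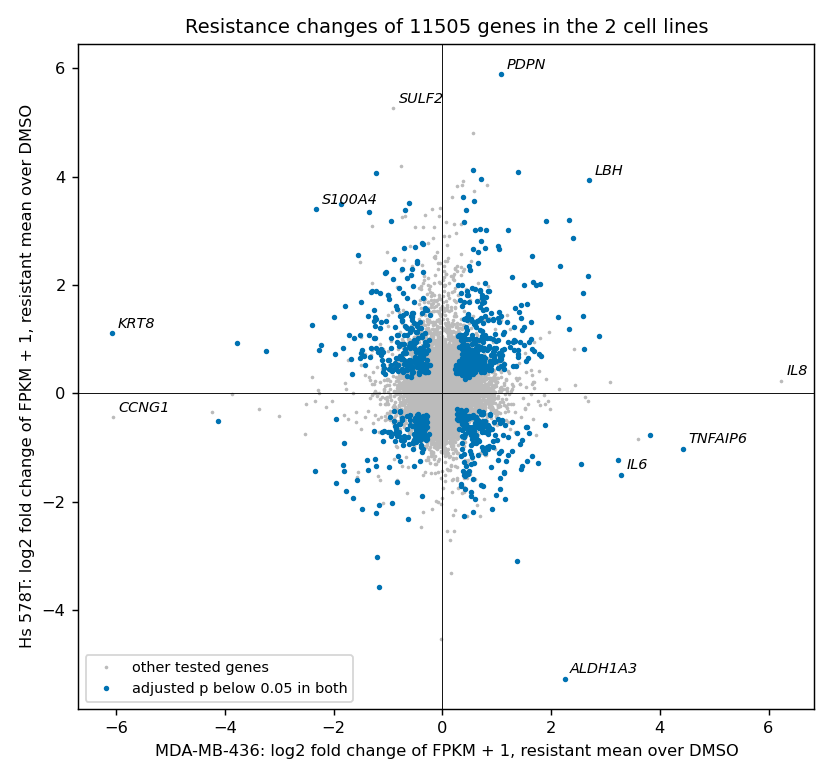
Log2 change of the resistant mean against DMSO in Hs 578T (vertical) and MDA-MB-436 (horizontal) for 11505 genes, on log2(FPKM + 1), with genes past the threshold of both cell lines in colour. Pearson's correlation across genes was 0.03.

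A small set of genes passed in all 6 resistant lines. It held 65 genes that rose, against 34.33 for independent lists, and 20 that fell, against 9.5. LBH, a transcriptional cofactor, rose by 2.69 in MDA-MB-436 and 3.93 in Hs 578T, EPB41L3 by 2.32 and 3.19, the protease ADAMTS9 by 2.16 and 2.34, and the metalloreductases STEAP1 and STEAP2 by 1.66 and 2.55 and by 1.66 and 2.06. BMF rose in all 6 lines, by 0.80 and 3.02. The metalloproteinase inhibitor TIMP3 fell by 1.77 and 1.80, DCBLD2 by 1.64 and 1.93, the Wnt antagonist SFRP1 by 1.81 and 1.44 and the adhesion molecule ALCAM by 1.83 and 1.32. The receptor kinase AXL fell by 0.83 and 1.63. Genes named in this paragraph were chosen after their values were seen, and each passed limma in every resistant line.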

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

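Tests chosen only after the result was seen are the gene lists tested on the differences between cell lines with their splits, the splits within replicate numbers, and both tests of the chromosome 5 interval.

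The resistance changes of the cell lines differed in 4199 genes by a direct test of the difference (limma, adjusted). No other split of the same libraries reached this count (1 of 100 splits, the real one, with 1683 the highest other). Chance in how these libraries were divided can therefore be excluded as its source. No label says that replicates were separate cultures, so these splits say nothing about chance differences between cultures. These splits ignore the replicate numbers. Of 100 splits that exchange labels within a number in each cell line only the real one reached it as well (highest other 1664), although in MDA-MB-436 the numbers do not pair R20C with DMSO. As Hs 578T minus MDA-MB-436, the named genes differed by 7.19 log2 units for KRT8, 6.17 for SULF2, 5.72 for S100A4, 5.62 for CCNG1, -7.51 for ALDH1A3, -5.99 for IL8, -5.45 for TNFAIP6 and -4.79 for IL6.

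6 gene lists differed in their resistance changes by camera. Interferon-stimulated genes had a median difference of 0.81 (30 of 49 higher in Hs 578T, 3 lower; camera adjusted p = 3.35e-05, and adjusted p = 0.516 with an estimated correlation), cancer-testis antigens of 0.85 (19 of 28 higher, none lower; camera adjusted p = 1.21e-09, and adjusted p = 0.00711 with an estimated correlation) and leukocyte and endothelial markers of 1.1 (5 of 7 higher, none lower; camera adjusted p = 0.00998, and adjusted p = 0.153 with an estimated correlation). Inflammatory genes had -0.79 (5 of 33 higher, 15 lower; camera adjusted p = 0.000153, and adjusted p = 0.631 with an estimated correlation), the integrated stress response -0.64 (none of 26 higher, 8 lower; camera adjusted p = 0.000817, and adjusted p = 0.631 with an estimated correlation) and mesenchymal genes -0.53 (4 of 30 higher, 14 lower; camera adjusted p = 0.000817, and adjusted p = 0.247 with an estimated correlation). Adjusted over the list alone the counts higher and lower were 32 and 4, 20 and 0, 5 and 0, 7 and 16, 0 and 8, and 5 and 14. In Hs 578T the cancer-testis rises were most frequent in R20C, where LCP1, TEK and CD3D were also highest. RNA from a further cell line was not excluded for them. Members of the cancer-testis and leukocyte lists near 0 in Hs 578T DMSO had little room to fall there, which limits what the absence of lower members shows. Chance cannot be excluded for the number of lists: 71 of 100 splits called as many as 6 lists, the highest other 13.

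The 72 h responses of the cell lines differed in 0 genes (limma; 159 at an unadjusted p under 0.05), as 100 of 100 splits reach by construction (highest other 1), and in 8 lists by camera. Their median differences were -0.10 for microtubule-associated proteins, -0.0919 for oxidative phosphorylation, -0.14 for the TCA cycle, -0.18 for cholesterol synthesis, -0.20 for mitosis, -0.34 for DNA replication, -0.11 for mesenchymal genes and -0.0747 for ribosomal proteins (camera adjusted p between 1.51e-07 and 0.0369). None of the 8 was called with an estimated correlation (camera adjusted p = 0.0786 for mesenchymal genes and 0.668 or more for the others), and the mesenchymal mean of -0.43 holds the FN1 values listed at 0. Without single libraries 3 to 11 lists were called: 3 without replicate 3 of treated MDA-MB-436, 4 without DMSO replicate 2 or 3 of Hs 578T and 5 without DMSO replicate 1 of MDA-MB-436. Chance cannot be excluded for this number of lists (39 of 100 splits, highest other 14).

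CCNG1, NUDCD2, HMMR and MAT2B, neighbours on chromosome 5, were nearly absent from all 9 resistant MDA-MB-436 libraries. The tables argue against genes missing from the annotation or removed by a filter, since the lowest mean of the 4 genes over the parental and Hs 578T groups was 13.971 FPKM. A candidate explanation is the loss of a DNA segment on all copies: no gene inside kept more than 0.645% of its DMSO level, and this was the only run of neighbouring genes lost to under 5% in either cell line. The interval holds only the 4 genes that define it, so the loss cannot be told apart from silencing of the interval without loss of DNA. Genes near PTTG1 on 1 side of it, such as THG1L (-1.255) and RNF145 (-0.804), fell by less. Whether the interval is part of a wider change was not tested. DNA was not measured, and whether the 3 lines descend from 1 cell that already lacked the interval was not tested.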

How the results depend on the processing

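Tests chosen only after the result was seen are replicates 2 and 3 alone, the block without replicate 3 of R20C of MDA-MB-436, the lists on the differences between cell lines, and leaving out genes at 0 beside a high library. Of 257 named-gene results under 5467 alternatives 5335 kept their side of the threshold, 131 lost the call, 1 gained it and 0 reversed. A reversal was counted only where the result was called in the main fit or in the alternative. Uncalled results that changed sign count as kept. Of 106 list results under 1850 alternatives 1733 kept their side of the threshold, 72 lost the call, 38 gained it and 7 reversed, by the direction of camera under the same rule. All 24 counts of genes and lists stayed within 1.5 times under a pseudocount of 0.1, rescaling and leaving out genes at 0 beside a high library, as did the 20 counts run with robust moderation, which left out the lists within each cell line. The calls lost most often were ABCC4 (13 alternatives), KDM4A (11), SLC2A3 in MDA-MB-436 (11), FOSB (9) and ZNF622 (9). Of the 24 counts, the 2-fold threshold and fitting the compared groups alone were run on 18, the block without replicate 3 of R20C on 14 and the estimated correlation on the 6 that count lists. No other pseudocount and no weighting of libraries was tried, and alternatives for count data did not apply. Where a filter or a fold threshold lowers a count, fewer genes can pass by construction; for the other changes the cause was not tested.

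In MDA-MB-436 the replicate block gave 3337 genes for R20A, 3622 for R20B, 3217 for R20C, 2322 in all 3 lines and 48 among the lines. The 2-fold threshold gave 448 for the resistant mean, 475, 487 and 426 for R20A, R20B and R20C, 297 in all 3 lines, 397 against 72 h of paclitaxel and 5 among the lines. An estimated correlation left 0 lists for the resistant mean and 0 for 72 h of paclitaxel. Fitting the compared groups alone gave 1519 for R20B, 858 for R20C and 2 among the lines (BST2 and SNORD94). The block without replicate 3 of R20C gave 6200 for the resistant mean, 5295, 5755 and 4328 for R20A, R20B and R20C, 3810 in all 3 lines, 6066 against 72 h of paclitaxel, 88 among the lines and 7 lists.

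In Hs 578T no filter gave 7 lists for the resistant mean. At least 5 FPKM in 3 libraries gave 2446 genes for the resistant mean, 1528 for R20A, 3111 for R20C, 596 in all 3 lines, 2536 against 72 h of paclitaxel and 3408 among the lines. The replicate block gave 4572 for R20A, 5020 for R20B, 1654 in all 3 lines, 3 for 72 h of paclitaxel and 8068 among the lines. The 2-fold threshold gave 1283, 1315, 1225 and 2284 for the resistant mean, R20A, R20B and R20C, 394 in all 3 lines, 1267 against 72 h of paclitaxel and 2584 among the lines. An estimated correlation left 0 and 0 lists. Fitting the compared groups alone gave 1789 for R20A and 1769 for R20B. Replicates 2 and 3 alone gave 6927 for the resistant mean, 6007 for R20A, 6320 for R20B, 2597 in all 3 lines, 8438 among the lines and 4 for 72 h of paclitaxel (SLC14A1, EGR1, HIST1H2BK and FN1, the last listed at 0 in both treated libraries). For the resistance difference between cell lines, at least 5 FPKM gave 2745, the 2-fold threshold 1761, replicates 2 and 3 alone 6575 and the block without replicate 3 of R20C 6405. For the 72 h difference no filter gave 2 (PECAM1 and MAATS1) and replicates 2 and 3 alone 2 (SLC14A1 and FN1).

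7 list results reversed at 72 h, by the direction of camera. Further medians changed sign without counting as reversed, such as oxidative phosphorylation (0.0011) and ribosomal proteins (0.0437) in MDA-MB-436 without DMSO replicate 2. The medians of the 7 were as follows. In MDA-MB-436 oxidative phosphorylation stood at 0.0533 and ribosomal proteins at 0.115 without replicate 1 of the treated cells, and oxidative phosphorylation at 0.0158 with replicates 2 and 3 alone. In Hs 578T inflammatory genes stood at -0.115 and ribosomal proteins at 0.165 without replicate 1 of the treated cells, and at -0.18 and 0.0256 with replicates 2 and 3 alone. Over all libraries left out in turn these medians ran in MDA-MB-436 from -0.0908 to 0.0533 (oxidative phosphorylation) and from -0.127 to 0.115 (ribosomal proteins), and in Hs 578T from -0.115 to 0.373 (inflammatory genes) and from -0.24 to 0.165 (ribosomal proteins).

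Leaving out each library in turn gave, in MDA-MB-436, 2048 to 3438 genes for the resistant mean (lowest without DMSO replicate 2), 1460 to 1841 for R20A, 1604 to 2474 for R20B, 1330 to 2051 for R20C (lowest without DMSO replicate 2), 1012 to 1644 in all 3 lines (lowest without DMSO replicate 2), 0 to 0 for 72 h of paclitaxel, 1880 to 3229 against it (lowest without its replicate 2), 2 to 19 among the lines, 4 to 7 lists for the resistant mean (highest without DMSO replicate 3) and 7 to 10 for 72 h. Among the lines the count was 9, 7 and 5 without replicates 1, 2 and 3 of R20A, 2 and 5 without replicates 2 and 3 of R20B, and 5 without replicate 2 of R20C, with BST2 in each set of 5 or fewer. In Hs 578T it gave 2782 to 4588 for the resistant mean, 1862 to 3361 for R20A (1862 and 1905 without its replicates 2 and 3), 1806 to 3756 for R20B (1806 without its replicate 2 or 3, 1863 without DMSO replicate 2), 3519 to 5210 for R20C, 612 to 1085 in all 3 lines (lowest without DMSO replicate 2), 0 to 1 for 72 h of paclitaxel (FN1, without its replicate 1), 2684 to 4510 against it (lowest without its replicate 2), 3953 to 5921 among the lines, 4 to 5 lists for the resistant mean and 5 to 11 for 72 h (5 without DMSO replicate 3 or treated replicate 1). The difference between cell lines gave 3420 to 4498 for resistance, 0 to 1 for 72 h (FN1, without replicate 1 of treated Hs 578T), and 5 to 7 and 3 to 11 lists, the 3 without replicate 3 of treated MDA-MB-436.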

Other observations

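Tests chosen only after the result was seen are the spread of chromosome 7 between libraries, its runs of genes in each cell line, the depth test library by library, the leukocyte genes, the MDA-MB-436 genes taken singly, and the splits within replicate numbers.

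The median change of genes differed between chromosomes in the resistant lines. As the median log2 change of a chromosome's genes minus that of the other autosomal genes, chromosome 7 stood at 0.346, 0.328 and 0.288 in R20A, R20B and R20C of MDA-MB-436 (387 genes) and at 0.451, 0.571 and 0.285 in those of Hs 578T (377 genes), against 0.013 and -0.008 after 72 h of paclitaxel. In MDA-MB-436 chromosomes 15 (0.488, 0.499 and 0.532) and 5 (0.251, 0.378 and 0.29), the latter holding the interval of CCNG1, were also higher, and chromosome 19 was lower in R20C (-0.322). In Hs 578T chromosome 9 was higher (0.436, 0.253 and 0.157), and chromosomes 3 (-0.399, -0.449 and -0.541), 10 (-0.208, -0.243 and -0.383) and 18 (-0.189, -0.325 and -0.748) were lower. Its chromosome 16 went both ways (0.163, -0.185 and 0.345), and in its R20B chromosomes 8, 22, 19 and 13 stood at 0.383, 0.302, 0.262 and -0.258. Runs of neighbouring genes were examined on chromosome 7 alone. Some list members named for MDA-MB-436 moved the same way as genes around them. COX5A lies on chromosome 15, RPS23 on chromosome 5 and OGDH (start 44646171) in the low run of chromosome 7 given below. FASTKD3 and NSUN2, listed beside MTRR, stood at -1.174 and -1.018. Whether position or list membership underlies these changes was not tested. Of 64 placed genes that rose in all 6 resistant lines 16 lie on chromosome 7, against 3.09 by its share of the genes (exact one-sided hypergeometric test, p = 3.86e-08, adjusted p = 1.7e-06 over 44 tests), among them STEAP1, STEAP2, ADAM22, KIAA1324L and ITGB8, chosen after their values were seen. The test takes genes as independent draws. Neighbours such as STEAP1 and STEAP2 may move together, so its p value may be too small.

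The rise of chromosome 7 genes as a group was found and weighed in the same data. The tables argue against GC content as the whole cause, since the lowest difference over the 6 lines was 0.315 with the GC trend removed, and against the spread between libraries, since the lowest resistant library stood at 0.273 and the highest parental one at 0.058. A candidate explanation is an extra copy of the chromosome: in Hs 578T the lowest run of neighbouring genes stood at 0.071, so no run lay below the genes elsewhere. That run (SE 0.081) and another at 0.141 (SE 0.107), both in R20C, cannot be told apart from no rise. The rise was also uneven, with runs of R20B from 0.198 (SE 0.076) to 0.834 (SE 0.069), so gain of the whole chromosome stays undecided there. In MDA-MB-436 the tables argue against gain of the whole chromosome, since the run with starts from 38217847 to 65216129 (GRCh37) stood at -0.504, -0.487 and -0.482, while gain of parts of it stays open. The test set in advance over both cell lines, with 3 of 54 runs at or below 0, decided neither way, and DNA was not measured.

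More genes reached 1 FPKM in R20A and R20C of Hs 578T than in its parental cells. The tables argue against depth library by library (12343 or more genes in the 2 libraries shallower than every DMSO library, which held at most 11211), scaling (at least 11947 after rescaling, against at most 11297) and admixed leukocytes (7 of their genes at a median of 1.02% of the LCP1 level in R20C, where LCP1 stood at 263 FPKM, PTPRC at 0.0984 and LYZ at 0.0334, though HLA-DRA was listed at 0 in DMSO and at 7.36 there, CD74 at 0.0171 and 2.7 and CORO1A at 0.77 and 3.68, while SRGN fell from 115 to 22.2). The mean depth ratio of 1.099 (SE 0.0823, 6 libraries) did not decide. Genes of MDA-MB-436 alone stood at medians of 1.98% of their MDA-MB-436 level in R20A, 0.378% in R20B and 8.94% in R20C (quartiles 0.523 and 15.1), R20A and R20C above the 1% set in advance as a bound, but 4 of the 12 stayed under 1% in R20C (AFAP1-AS1, CDKN2A, MAGEA10 and PLIN2), which argues against admixed MDA-MB-436 cells as the whole source there. Admixture of another line and broader transcription in these lines stay open.

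After 72 h of paclitaxel no gene was called in either cell line without the replicate number in the fit (limma; 82 and 399 genes at an unadjusted p under 0.05), and with it as a block none in MDA-MB-436 and 3 in Hs 578T. Of genes changed 2-fold 69.5% were recovered in simulated MDA-MB-436 libraries and 49% in simulated Hs 578T libraries. The correlation of 0.36 between the cell lines' 72 h changes was reached by 17 of 100 pairs of splits that ignore the replicate numbers (highest other 0.685). The numbers pair these libraries in both cell lines, and of the 16 pairs of splits that keep to them 3 were as high (highest other 0.373). Chance cannot be excluded for it.

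Other splits of the same libraries give the following. They test chance in how these libraries were divided, not chance differences between cultures. Chance can be excluded, with 1 of 100 splits as large, for the resistant mean against DMSO in MDA-MB-436 (3086 genes, highest other 1153) and Hs 578T (4094, 971), for genes called in all 3 lines (1528, 0 and 941, 172), for the resistant mean against 72 h of paclitaxel (2890, 1950 and 4128, 3275) and for differences among the Hs 578T lines (5350, 2373). It cannot be excluded for differences among the MDA-MB-436 lines, where 5 of 100 splits called at least 14 genes and 1 called 370, several times the real count. That split put the replicate 1 libraries of R20A, R20B and R20C together in one set, which points to a structure of the samples other than the lines; its origin was not tested. With the replicate number as a block 48 genes differed among the lines, although the numbers do not pair R20C there. Nor can it be for the number of lists called in the resistant mean, where 75 of 100 splits in MDA-MB-436 called as many as 4 (highest other 10) and 89 of 100 in Hs 578T (4, 12). List by list, the inflammatory, interferon-stimulated, stress response and ribosomal medians of MDA-MB-436 were each reached by 1 of 100 splits, the real one. So were its methionine, Polycomb and mesenchymal medians, which camera did not call. In Hs 578T the called cancer-testis, mesenchymal, ribosomal and DNA replication medians were reached by 11, 17, 30 and 38 of 100 splits. 10 splits are too few for R20A, R20B and R20C against DMSO (2189, 2395 and 2086 genes in MDA-MB-436, highest others 0, 1 and 0, and 2868, 2944 and 4922 in Hs 578T, highest others 13, 0 and 0), for 72 h of paclitaxel (0 genes, highest other 1 in each cell line) and for its lists (9 in MDA-MB-436, highest other 7, and 11 in Hs 578T, highest other 12, with 2 of 10 splits as large). In Hs 578T the replicate numbers pair the libraries. Splits that exchange labels within a number gave as many genes 1 time in 100 for the resistant mean (highest other 3540). For all 3 lines it was 2 in 100 (highest other 1047). In both cases the highest took a whole other group as the control. The count of 941 over all 3 lines is therefore not particular to DMSO as the control. For the resistant mean another group as the control still gave 3540 genes, against 4094 with DMSO.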
